A study of Mus musculus with 12 samples.

How the data were processed

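RNA was measured in gonads of mouse embryos at 14.5 days post coitum on the Affymetrix Mouse Transcriptome Array 1.0, a 1-colour array that reads transcripts with many short probes. Per the labels' protocols, 1 pair of gonads was freed of the mesonephros for each sample and stood for 1 biological replicate, RNA was extracted with the Picopure kit and checked on a BioAnalyzer, and 100 ng was amplified and biotin-labelled with the WT Plus kit. The embryos came from 1 cross, between mice carrying Sf1-cre and mice carrying a Rosa26 allele that holds Foxl2 behind a CAG promoter and a stop cassette that Cre removes. Sf1-cre acts in the somatic cells of the fetal gonad. All embryos used carried Sf1-cre, and the group named XY FOXL2+ also carried the Rosa26 Foxl2 allele. The strain background was mixed 129Sv and C57Bl/6J. The 3 groups, taken from the sample titles, were XY control, XY FOXL2+ and XX control, with 4 arrays each. No litter, day or batch is given in the sources used here.

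The deposited values are on a log scale and were taken as log2, because they run from 2.60 to 19.49 on arrays whose medians lie between 6.149 and 6.296. The base of the logarithm, the background correction, the summarization over probes and the normalization by the authors are not given in the sources used here. If the base were another, every log2 change and fold below would change scale and the tests would not. The deposited table carries no detection calls, so a low signal cannot be told from background on a single gene, and changes of genes near the floor are compressed. Background control probe sets had medians between 3.99 and 4.17 on the 12 arrays, but genes that should be silent read higher on average: Eif2s3y 5.99, Uty 6.24, Kdm5d 6.27 and Uba1y 6.94 in XX controls and Xist 7.07 in XY controls. The cluster named Sry read 9.43 in XX controls, which lack the gene. Its signal was alike in all groups, and in XX controls its probes read something other than Sry. The level at which a silent gene reads thus differs by cluster and is not known for any one, low signals are not shown to be above background here, and a fold that starts or ends at such a level is a lower bound. The precision of each value is limited by the number of arrays.

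The table has 72688 entries, of which 6732 are control probe sets that were left out, and 65956 transcript clusters were tested with no filter on low signal. A transcript cluster is the array's unit for 1 locus. Gene symbols came from the platform annotation, updated through the RefSeq table: 31258 clusters have 1 symbol, 1492 have several and were left unnamed, and 33206 are not listed there and are unnamed here. These symbols name 30702 genes, 441 of them with over 1 cluster, and 1152 older symbols were updated. Where a gene has several clusters, the one with the highest mean over the 12 arrays stands for it. No genome build is given in the sources used here, so no coordinates are used. Probes of near-identical gene copies can take up each other's transcripts, and whether the Foxl2 probes read the transgene, the endogenous gene or both is not given in the sources used here.

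Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) in 1 fit over all 12 arrays, which leaves 9 residual degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 65956 clusters, with a threshold of 0.05. The 3 comparisons were XY FOXL2+ minus XY control (called the FOXL2 effect), XX control minus XY control (the sex difference), and XY FOXL2+ minus XX control. Clusters past the threshold and at least 2-fold apart in the sex difference are called sex-biased. The position of an array is its weighted mean place between the XY mean (0) and the XX mean (1) over such clusters, each control array being left out of its own group's mean. Single values and list scores (the mean log2 value of the members on 1 array) were compared by exact permutation of 4 against 4 arrays, with 70 assignments and a smallest two-sided p of 0.0286. The p-values of list scores were adjusted over the 26 lists of a comparison. All lists of a comparison that reach the smallest p share the same adjusted p, which depends on how many lists reach it. Such lists therefore pass or fail together. Chance alone gives 2.86% of genes whose groups of 4 do not overlap.

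The 26 gene lists hold 308 distinct genes, 263 with a cluster of their own. They are Sertoli cell, fetal granulosa cell, postnatal granulosa cell, fetal Leydig cell and steroidogenesis, cholesterol synthesis, hedgehog response, WNT response, BMP response, retinoic acid metabolism, general germ cell, meiotic germ cell, male germ cell, peritubular myoid and smooth muscle, interstitial progenitor, endothelial, macrophage and leukocyte, erythroid, mesonephric duct and tubule, adrenal cortex, neural crest and glia, basement membrane, mitotic cell cycle, immediate early and stress, ribosomal protein, Y-linked, and X inactivation and escape. The fetal granulosa and WNT lists share members. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, with camera at an estimated correlation and fry beside it. Because the samples are whole gonads, a list's change can come from the number of cells of a type or from their expression.

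The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names 36 key genes (32 with a cluster of their own; Insl3, Pdgfra, Cyp19a1 and Ddx3y are not analysed here), the 5 genes with the largest rise and the 5 with the largest fall among called genes whose groups do not overlap, up to 4 called members per list with any that go the other way, and the 4 highest and 4 lowest genes outside the range between the controls. Genes named outside this rule are marked where they appear.

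Alternatives were a filter at the median signal, clusters with 1 symbol only, quantile normalization of the deposited values, centring of each array on its median, eBayes without the trend or in its robust form, array weights, a fit on the 2 groups compared, the replicate number as a block, a 2-fold threshold, other fold thresholds for sex bias, other set tests and gene summaries, and leaving out each array in turn. Because the FOXL2 effect and the sex difference share the XY controls, unchanged groups were simulated against these arrays in 20 data sets, and the XY controls were split into pairs so that the comparisons shared no array, in all 6 ordered ways. The test of the FOXL2 effect was tried on simulated data over 65956 clusters, with independent noise and 1 pooled SD per cluster for all groups. There it recovered 90% of 100 clusters changed by a log2 of 1 and 99% of 100 changed by a log2 of 2, with 15 false calls among 204. The real XY FOXL2+ arrays varied more (median SD 0.163, against 0.131 in XY controls and 0.116 in XX controls), so these rates need not hold for them.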

Results

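Gene expression was measured in fetal mouse gonads to ask what the transcription factor FOXL2, which marks the granulosa cells of the ovary, does when its gene is switched on in the somatic cells of an XY gonad. XY FOXL2+ gonads were set against XY control gonads and against XX control gonads, with 4 arrays per group and 1 embryo per array. Spearman correlations between arrays of a group over all clusters were 0.986 to 0.992 in XY controls, 0.981 to 0.991 in XY FOXL2+ and 0.992 in XX controls. The median SD of a cluster within a group was 0.131, 0.163 and 0.116 on the log2 scale in the same order. The first principal component held 51.5% of the variance and placed the XY FOXL2+ arrays between the controls. XY FOXL2+ replicate 1 stood apart from all other arrays on the second component (14.1% of the variance), at -76.9 against -22.1 to 22.6. On the third component (10.5%) XY FOXL2+ replicates 3 and 4 stood apart together, at -49.7 and -44.2 against -12.7 to 35.6.

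Foxl2 itself was higher in every XY FOXL2+ array than in every XY control. Its signal was 5.35 ± 0.21 in XY controls, 7.55 ± 0.81 in XY FOXL2+ and 7.48 ± 0.42 in XX controls (log2, SD, n = 4). The XY FOXL2+ arrays read 7.67, 8.62, 7.18 and 6.72. The difference from XY controls was 2.20 (SE 0.33, adjusted p = 0.00122, exact permutation p = 0.0286), a rise of at least 4.59-fold since the XY value lies where silent genes read, and that from XX controls was 0.07 (adjusted p = 0.943). Sex chromosome genes followed the labels on all 12 arrays: Xist, the RNA that silences an X chromosome in XX cells, read 16.27 ± 0.07 in XX controls against 7.07 ± 0.22 in XY controls and 6.84 ± 0.71 in XY FOXL2+. The Y-linked genes Uty, Kdm5d and Eif2s3y were higher in every XY array than in every XX array. The cluster named Sry read 9.39, 9.46 and 9.43 in XY control, XY FOXL2+ and XX control, so it did not separate the sexes. It stays among the 8 measured members of the Y-linked list, and its XX signal is used below where a signal floor is weighed.

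In XY FOXL2+ gonads genes of steroid synthesis and many Sertoli cell genes fell, and genes of meiosis rose. Cyp11a1, which makes the first steroid from cholesterol, read 17.03 ± 0.14 in XY controls and 8.89 ± 2.29 in XY FOXL2+ (n = 4), a log2 change of -8.14 (SE 0.79, adjusted p = 3.65e-05). Cyp17a1, the next enzyme toward androgens, changed by -6.90 (0.000523) and Star, which carries cholesterol into mitochondria, by -6.38 (1.3e-09), where values in brackets are adjusted p. Amh, the Sertoli hormone that makes the Müllerian duct regress, read 12.54 ± 0.44 in XY controls and 7.06 ± 1.17 in XY FOXL2+, a change of -5.48 (SE 0.44, 7.3e-06). Stra8, which germ cells need to enter meiosis, rose from 6.31 ± 0.09 to 12.14 ± 0.87 (5.83, SE 0.32, 3.43e-07), where 6.31 is a level at which Y-linked genes read in XX arrays, so that the 57.1-fold change is a lower bound.

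In total 1621 transcript clusters were higher and 3077 lower in XY FOXL2+ than in XY controls, with 386 and 721 of them at least 2-fold apart. Among clusters with 1 gene symbol these were 1036 and 1449 genes. The largest rises were those of Stra8, Meioc (31.9-fold, from a like level), M1ap (4.46), H2ac1 (4.02) and Bhmg1 (3.69), and the largest falls those of Cyp11a1, Cyp17a1, Adh1 (-6.59), Star and Amh. Higher calls made up 34.5% of the total, and 45.1% after quantile normalization (2184 higher, 2656 lower). Without XY control replicate 3 the number of higher clusters was 998, and without replicate 4 it was 1051. With only the 2 groups compared 809 were higher and 1891 lower.

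**Figure D1:**
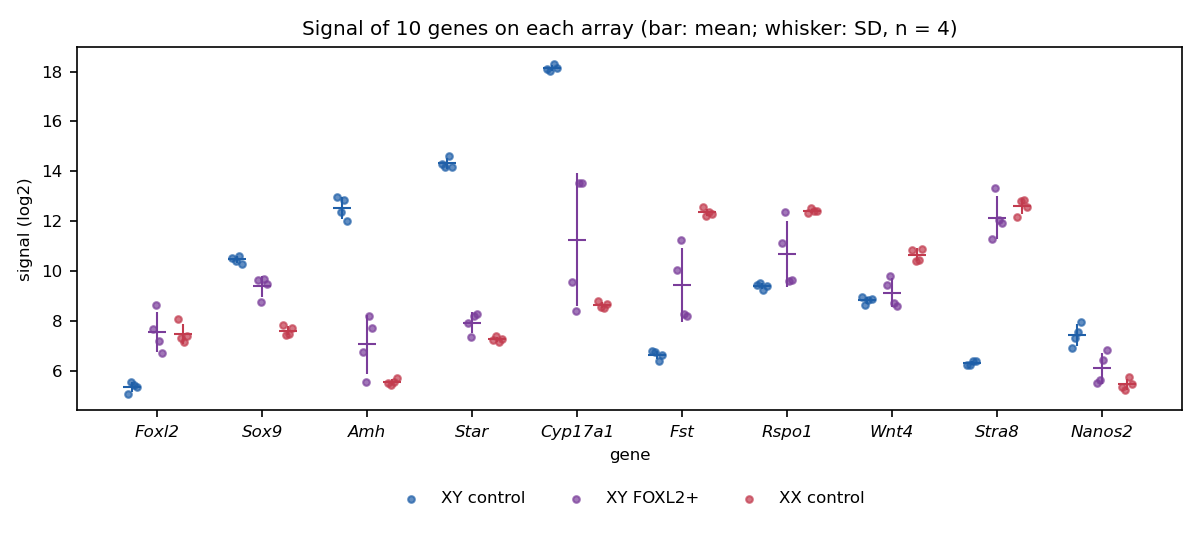
Signal (log2, vertical axis) of 10 genes on each of the 12 arrays, with a bar at the mean and a whisker of 1 SD (n = 4 per group). In XY FOXL2+ Star lies at 7.93 ± 0.43, near the XX controls (7.25 ± 0.11) and far from the XY controls (14.31 ± 0.22), whereas Sox9 at 9.39 ± 0.42 and Wnt4 at 9.13 ± 0.58 lie nearer to the XY controls.

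Of the 22 Sertoli cell genes measured, 15 fell, none rose and 7 did not pass. Adjusted over the list alone, 19 fell. Besides Amh, the largest falls were those of Hsd17b3 (-5.36), which reduces androstenedione to testosterone, Ptgds (-2.89) and Cst9 (-2.52). Sox9, the transcription factor that drives Sertoli cell fate, fell 2.11-fold (-1.08, SE 0.18, adjusted p = 0.00262), Dhh, the hedgehog ligand of Sertoli cells, fell by 1.77 (0.00833) and Sox8 by 0.84 (0.0298). Fgf9 (0.17, 0.488), Dmrt1 (-0.42, 0.265) and Inhbb (-0.51, 0.38) did not pass. The list had a mean change of -1.55 (camera adjusted p = 1.28e-17, adjusted p = 0.0695 with an estimated correlation). Cst9 and Sox8 lost their calls without single arrays, with adjusted p up to 0.0884 and 0.0943, and in the fit on only the 2 groups compared (0.11 and 0.102).

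Of 17 fetal granulosa cell genes measured 4 rose: Fst (2.80, 0.00523), the activin antagonist follistatin, Runx1 (1.22, 0.0115), the WNT feedback gene Nkd1 (0.99, 0.00128) and Bmp2 (0.73, 0.00114). Runx1 lost its call with only the 2 groups compared (0.0508). Adjusted over the list alone 7 rose. Rspo1 (1.29, 0.125), Irx3 (0.94, 0.119) and Wnt4 (0.30, 0.537) did not pass. In Rspo1 the arrays read 11.14, 12.35, 9.60 and 9.66 against 9.23 to 9.50 in XY controls. The mean change of the list was 0.64 (camera adjusted p = 0.000145, adjusted p = 0.42 with an estimated correlation). Among 10 genes of the postnatal granulosa cell Inha fell (-3.00, 5.56e-05) and Ccnd2 rose (0.50, 0.0078), Esr2 did not pass (1.08, 0.229; with array weights 1.64, 0.0206), and the list was not called (0.131).

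Leydig cell and cholesterol genes fell together. Of 11 fetal Leydig cell and steroidogenesis genes 9 fell, also when adjusted over the list alone, including Hsd3b1 (-3.53, 0.000749), with a mean of -3.46 (camera adjusted p = 3.45e-18, and 0.0155 with an estimated correlation). All 18 measured genes of cholesterol synthesis fell, led by Lss (-2.90), Fdps (-2.51), Msmo1 (-2.37) and Hsd17b7 (-2.33), with a mean of -1.77 (7e-39, and 0.0147 with an estimated correlation). Nr5a1, the SF1 gene that runs steroidogenic genes and whose promoter drives the Cre, fell by 1.68 (SE 0.08, 6.4e-08), with 11.71 ± 0.08 in XY FOXL2+ against 13.39 ± 0.09 in XY controls and 12.14 ± 0.03 in XX controls. Of 5 adrenal cortex genes 3 fell, Cyp11b1 (-3.73), Cyp21a1 (-0.92) and Cyp11b2 (-0.71), both over all clusters and adjusted over the list alone (mean -1.16, camera adjusted p = 1.45e-06, and 0.0147 with an estimated correlation). These 3 lists were the only ones of the 13 called in this comparison whose call held with an estimated correlation.

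Hedgehog targets and genes of myoid and interstitial cells were lower as well. In the hedgehog response list 3 of 5 genes fell, Hhip (-2.78), Gli1 (-1.31) and Ptch1 (-1.29), both over all clusters and adjusted over the list alone (camera adjusted p = 0.0207, adjusted p = 0.189 with an estimated correlation). The list was no longer called without XY FOXL2+ replicate 1 (0.0845), and Hhip and Gli1 lost their calls without single arrays, with adjusted p up to 0.0605 and 0.0567. With only the 2 groups compared Hhip (0.0865), Gli1 (0.0831) and Ptch1 (0.0661) all lost their calls. Of 8 peritubular myoid and smooth muscle genes 5 fell, the same number as adjusted over the list alone, among them Acta2 (-1.59), Tagln (-1.55), Myh11 (-1.16) and Cnn1 (-0.78) (1.48e-06, adjusted p = 0.0695 with an estimated correlation). Of 5 interstitial progenitor genes Wnt5a (-1.81), Dlk1 (-1.19) and Nr2f2 (-0.61, 0.0484) fell and Maf rose (0.65, 0.0227). Adjusted over the list alone 4 fell and 1 rose (list adjusted p = 0.00314, adjusted p = 0.276 with an estimated correlation). Nr2f2 and Maf lost their calls without single arrays, with adjusted p up to 0.125 and 0.0793, and with only the 2 groups compared (0.132 and 0.0652), Nr2f2 also after quantile normalization (0.0742) and with array weights (0.109).

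Germ cell genes moved by class. Of 20 meiotic genes 15 rose, and 18 adjusted over the list alone, among them Stra8, Meioc, Smc1b (3.68) and Meiob (3.18), with a mean of 2.09 (camera adjusted p = 3.83e-17, adjusted p = 0.162 with an estimated correlation). Of 8 male germ cell genes Nanos2 (-1.35, 0.00997), which holds XY germ cells out of meiosis, and Lefty2 (-1.16, 0.00486) fell, and 6 fell adjusted over the list alone (0.00011, adjusted p = 0.0695 with an estimated correlation). Cyp26b1, the enzyme that degrades retinoic acid in the fetal testis, fell 4.63-fold (-2.21, SE 0.23, 8.08e-05). In the retinoic acid list Aldh1a1 fell as well (-1.32) and Rarb rose (0.99), 3 of 11 rose and 3 fell adjusted over the list alone, and the list was not called (0.945). Its score changed by -0.09, which passed by exact permutation (adjusted p = 0.0496). The groups barely separated, with 8.428 on XY FOXL2+ replicate 1 against 8.432 on XY control replicate 4. Of 11 general germ cell genes Dnd1 (-0.89) and Sall4 (-0.73, 0.0348) fell, 3 fell adjusted over the list alone, and Ddx4 did not pass (-0.16, 0.779). That list was called lower (0.0385, adjusted p = 0.602 with an estimated correlation), but not without XY control replicate 4 (0.244) or XY FOXL2+ replicate 1 (0.599), nor with fry (0.238). It did not pass by exact permutation of the list scores either (adjusted p = 0.495). XY FOXL2+ replicate 1 had the lowest general germ cell score of its group, 9.41 against 10.1 to 10.35, and the lowest meiotic score, 9.48 against 10.39 to 11.55.

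Most other lists showed no call. BMP response was called higher (0.0123, adjusted p = 0.17 with an estimated correlation), with Id2 (1.25) and Id3 (0.80) up and Smad7 (-0.47, 0.0396) down, and 3 up and 1 down adjusted over the list alone. Macrophage and leukocyte genes were called higher (5.79e-05, adjusted p = 0.189 with an estimated correlation), with 4 of 13 up, C1qb (0.74), Mrc1 (0.55), Adgre1 (0.38) and Csf1r (0.36, 0.0268), and 6 adjusted over the list alone. By exact permutation of the list scores this list did not pass (adjusted p = 0.0928). Of the lists called by camera in this comparison, all but this one and general germ cell passed that test (adjusted p = 0.0496 each). They all had the smallest possible p of 0.0286, so they share the same adjusted p and pass or fail together. These passes thus lend little support to any single list. The lists not called by camera were WNT response (0.145), endothelial (0.607), erythroid (0.963), mesonephric duct and tubule (0.82), neural crest and glia (0.22), basement membrane (0.145), mitotic cell cycle (0.346), immediate early and stress (0.22), ribosomal protein (0.945), Y-linked (0.441), and X inactivation and escape (0.994). Adjusted over the list alone, 3 WNT genes rose and 1 fell, 6 endothelial rose and 2 fell, 3 mesonephric rose and 2 fell, 3 basement membrane rose and 5 fell, 1 mitotic gene fell and 2 stress genes fell, and none changed in the others. Single members that passed over all clusters were Nkd1, Emcn (0.76), Cldn5 (0.73) and Ramp2 (0.54) among the WNT and endothelial genes, Calb1 (2.77), Ret (-0.77) and Lhx1 (-0.60) among the mesonephric, and Col4a1 (-1.40), Col4a2 (-1.18) and Lama1 (0.42), which encode basement membrane proteins. Cenpf (-0.46), a mitotic gene, and the heat shock gene Hspa1a (-1.84) passed too. The calls of Smad7, Sall4, Csf1r, C1qb, Emcn, Ramp2, Ret, Lhx1, Lama1 and Cenpf ended without single arrays, with adjusted p up to 0.118. Those of Smad7 (0.121), Sall4 (0.0712), Emcn (0.0699), Lhx1 (0.0741) and Lama1 (0.115) ended with only the 2 groups compared, and those of Smad7 (0.116) and Sall4 (0.0588) after quantile normalization, Sall4 also with array weights (0.0675). The immediate early and stress list was called lower with members above the median signal only (0.0377) and with fry (0.00395), and the basement membrane list with fry (0.0464). By exact permutation of the list scores these lists and neural crest and glia were lower (adjusted p = 0.0496 each). The mean, the median and the test differed in sign for retinoic acid metabolism (mean -0.09, median 0.02, test lower), erythroid (0.11, 0.04, lower), ribosomal protein (mean -0.00031, median 0.0027, lower), and X inactivation and escape (0.01, 0.005, lower).

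**Figure D2:**
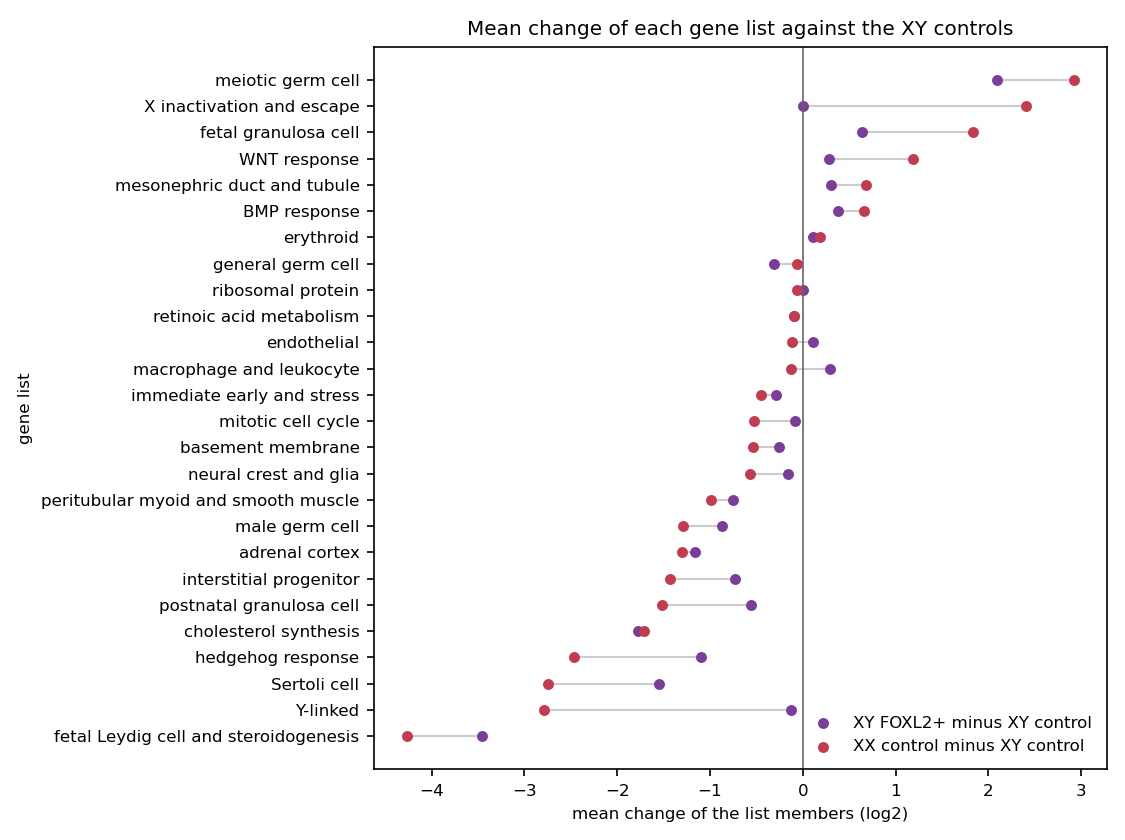
Mean log2 change of the members of each of the 26 gene lists (horizontal axis) in XY FOXL2+ and in XX controls, both against XY controls. The cholesterol synthesis list changed by -1.77 in XY FOXL2+ and -1.71 in XX controls, the meiotic list by 2.09 and 2.92, and the fetal granulosa list by 0.64 and 1.83.

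In the sex difference, which gives the scale for the FOXL2 effect, XX gonads were lower than XY gonads in Cyp11a1 (-10.73, SE 0.79, adjusted p = 2.19e-06), Cyp17a1 (-9.52), Hsd17b3 (-8.23), Cst9 (-7.30), Star (-7.06) and Amh (-6.99), and in Sox9 (-2.86, SE 0.18, 5.65e-07), Dhh (-4.14) and Nr5a1 (-1.24). They were higher in Xist (9.19), Meioc (6.41), Stra8 (6.29), M1ap (6.11) and Fst (5.71, SE 0.51, 9.8e-06), and in Lgr5 (3.89), Rspo1 (3.01), Runx1 (2.68), Wnt4 (1.82) and Foxl2 (2.13, 0.000507). In all 4727 clusters were higher and 6732 lower in XX, 1140 and 1709 of them at least 2-fold. Higher calls made up 41.3%, and 53.2% after quantile normalization (6116 higher, 5385 lower).

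Of the Sertoli genes 21 of 22 were lower in XX (camera adjusted p = 9.96e-20, and 0.0452 with an estimated correlation). All 18 cholesterol genes were lower (1.87e-22, and 0.0332 with an estimated correlation), as were 9 of 11 Leydig genes (2.53e-12, and 0.0332 with an estimated correlation) and 4 of 5 adrenal cortex genes (4.06e-05, and 0.0252 with an estimated correlation). Y-linked genes were lower (6 of 8, 5.31e-09, and 0.0252 with an estimated correlation), and X inactivation and escape genes higher (4 of 5, 7.24e-06, and 0.0235 with an estimated correlation), with Kdm6a (1.42) and Kdm5c (0.61) beside Xist. These 6 of the 18 calls held with an estimated correlation. Called higher without holding so were fetal granulosa (14 of 17 up, with Fzd1 down, -0.42, and adjusted p = 0.0785 with an estimated correlation), WNT response (6 of 9 up, Lef1 2.06 and Axin2 2.02, 0.0785), BMP response (5 of 10 up, Msx1 1.97 and Msx2 1.59, 0.0635) and meiotic germ cell (19 of 20 up, 0.0785). Called lower in the same way were postnatal granulosa (7 of 10 down, Hsd17b1 -3.85, Inha -3.93, Inhba -2.59 and Fshr -2.34, with adjusted p = 0.224 with an estimated correlation), hedgehog response (3 of 5, 0.0891), male germ cell (7 of 8, Piwil4 -2.76 and Nanos2 -1.99, 0.0556), myoid (6 of 8, Acta2 -2.35, 0.0635), interstitial progenitor (4 of 5, Wnt5a -2.37 and Tcf21 -1.86, 0.114), mitotic cell cycle (9 of 13, Aurkb -1.34 and Cdk1 -1.03, 0.195), neural crest and glia (2 of 4, Erbb3 -1.74 and Th -0.42, 0.182) and basement membrane (5 of 11 down and 2 up, Nid1 -1.34, Lamb1 -1.18, Lama1 0.45 and Col4a5 0.44, 0.378). Neural crest lost its call without XX control replicate 1 (0.05), and basement membrane without XY control replicates 1 (0.0526) or 2 (0.0525) or XX control replicates 3 (0.0989) or 4 (0.0553). The calls of Fzd1 and Lama1 ended without single arrays, with adjusted p up to 0.0937 and 0.0512, and that of Fzd1 after quantile normalization (0.0592). Adjusted over the list alone, all 22 Sertoli, 8 male germ cell and 20 meiotic genes passed in the direction of their list, as did 15 fetal granulosa genes (1 against), 7 WNT (2 against), 11 mitotic (1 against), 7 basement membrane (3 against), 7 myoid and 7 Y-linked genes. The other 8 lists were not called. Among them mesonephric duct and tubule (0.00536) and immediate early and stress genes (0.0111) were called with members above the median signal only, and these (0.0162 and 7.07e-05), retinoic acid metabolism (0.0143) and endothelial genes (0.0226) with fry. By exact permutation of the list scores all lists called by camera passed, as did mesonephric duct and tubule (higher) and immediate early and stress genes (lower, adjusted p = 0.0372 each). The mean, the median and the test differed in sign for retinoic acid metabolism (-0.09, 0.05, higher) and macrophage and leukocyte genes (-0.13, 0.01, higher).

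Against XX controls, 11 of 22 Sertoli genes were higher in XY FOXL2+ gonads and 11 of 17 fetal granulosa genes lower, and the lists were called (8.08e-11 and 3.78e-13) but not with an estimated correlation (adjusted p = 0.21 and 0.168). The Leydig list was called higher (0.00846) and the meiotic list lower (7.97e-09), neither with an estimated correlation (0.296 and 0.252), with 2 of 11 and 1 of 20 genes past the threshold. By exact permutation of the list scores neither passed (adjusted p = 0.148 and 0.177). Sox9 was 3.43-fold higher in XY FOXL2+ (1.78, SE 0.18, adjusted p = 0.000188), Cst9 27.6-fold (4.79, 0.00122), Mmd2 8.34-fold (3.06, 0.000581) and Dhh 5.18-fold (2.37, 0.0022), and Amh did not pass (1.51, 0.0659) but was called with array weights (1.89, 0.0047) and with clusters above the median signal only (0.0475). Fst was 7.56-fold lower (-2.92, SE 0.51, 0.00561), with Lgr5 (-2.80), Lef1 (-2.32), Wnt4 (-1.52, 0.00244), Runx1 (-1.46) and Bmp2 (-1.08) lower as well. Cyp11a1 (2.59, 0.0817), Cyp17a1 (2.62, 0.134), Hsd3b1 (1.20, 0.207) and Stra8 (-0.45, 0.51) did not pass, with SDs in XY FOXL2+ of 2.29, 2.67, 1.38 and 0.87. Array weights were 0.296, 0.506, 1.12 and 1.18 for XY FOXL2+ replicates 1 to 4. They thus favoured replicates 3 and 4, which had moved least toward XX. Cyp11a1 read 7.69, 6.26, 10.68 and 10.92 on these 4 arrays. With these weights Cyp11a1 (3.46, 0.00305), Cyp17a1 (3.69, 0.00529) and Hsd3b1 (1.81, 0.00841) were called higher than in XX, as were Ptgds (0.00295), Sox8 (0.00774), Inhbb (0.0148), Nanos2 (0.0365) and Acta2 (0.012), and Irx3 lower (0.00522). Of the meiotic genes only Rec8 passed (-1.91, 0.00337), and 12 of 20 were lower adjusted over the list alone.

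In total 1891 clusters were higher and 1744 lower in XY FOXL2+ than in XX, 566 and 410 at least 2-fold. Array weights gave 3668 and 3084, and the fit on only the 2 groups compared 944 and 972. The largest rises were those of Eif2s3y (5.11), Uty (4.90), Cst9, Uba1y (4.57) and Kdm5d (4.27), and the largest falls those of Xist (-9.42), the imprinted gene Phlda2 (-4.07), Fst, Lgr5 and the long noncoding RNA Rmst (-2.69). Higher calls made up 52%, and 41.5% with each array centred on its median (1540 higher, 2172 lower). Without XY FOXL2+ replicate 2 the counts were 2967 higher and 3025 lower, without replicate 3 1123 and 1132, without replicate 4 980 and 1032, and without XX control replicates 2, 3 and 4 they were 1008 and 1033, 981 and 1087, and 1142 and 1073.

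Of the lists only Y-linked (6 of 8 up, camera adjusted p = 5.89e-13, and 0.00933 with an estimated correlation) and X inactivation and escape (3 of 5 down, 3.27e-09, and 0.00348 with an estimated correlation) held with an estimated correlation among the 17 called in this comparison. Called higher in XY FOXL2+ were Sertoli (11 of 22 up, 18 adjusted over the list alone, adjusted p = 0.21 with an estimated correlation), postnatal granulosa (2 of 10, Esr2 1.81 and Nr5a2 0.63, 0.252), Leydig (2 of 11, Hsd11b2 1.02 and Star 0.67, 0.296), hedgehog response (3 of 5, Hhip 3.36, 0.21), interstitial progenitor (3 of 5, Tcf21 1.13, 0.252), endothelial (5 of 17, Cldn5 0.87 and Tek 0.74, 0.252), macrophage and leukocyte (4 of 13, Lyz2 2.09, 0.21), mitotic cell cycle (6 of 13, Aurkb 0.90 and Cdk1 0.81, 0.252), neural crest and glia (Erbb3 1.39, 0.252) and male germ cell (0 of 8, 0.252). Called lower were fetal granulosa (11 of 17 down, 14 adjusted over the list alone, 0.168), WNT response (5 of 9, Axin2 -1.50, 0.108), BMP response (3 of 10, Msx1 -1.47, 0.252), meiotic (0.252) and general germ cell (0 of 11, 0.495). In XY FOXL2+ replicate 1 the mitotic score was 12.45 against 11.94 to 12.01 in the other arrays of its group. With single arrays left out the calls ended for male germ cell (XY FOXL2+ 3 0.0972 and 4 0.114, XX control 1 0.0553, 2 0.0506 and 4 0.0529), general germ cell (XY FOXL2+ 1 0.426, XX control 2 0.0798 and 3 0.108), BMP response (XY FOXL2+ 1 0.0577 and 2 0.127, XX control 1 0.0973) and neural crest (XY FOXL2+ 3 0.0561 and 4 0.0751, XX control 1 0.0833). Of the genes named here Esr2, Star and Lyz2 also lost their calls without single arrays, with adjusted p up to 0.131, 0.143 and 0.121, and with only the 2 groups compared (0.133, 0.0993 and 0.0769), Star also with arrays centred on their median (0.0534). After quantile normalization BMP response (0.129), general germ cell (0.109) and neural crest (0.0858) were not called, with fry general germ cell (0.393), meiotic (0.0547) and male germ cell (0.0531) were not, and with members above the median signal only male germ cell was not (0.335). By exact permutation of the list scores Leydig (adjusted p = 0.148), meiotic (0.177), male germ cell (0.0825) and general germ cell (0.419) did not pass, and the other called lists did (0.0496 each). These passes again share the same adjusted p, which the Y-linked and X inactivation and escape lists help to lower. With arrays centred BMP response and general germ cell were not called (0.11 each). Called only under an alternative were basement membrane (0.0314 after quantile normalization, 0.0327 centred), mesonephric duct and tubule (0.00111 with members above the median signal only) and immediate early and stress genes (0.0358 with fry). By exact permutation of the list scores adrenal cortex was higher and mesonephric duct and tubule lower (adjusted p = 0.0496 each). Retinoic acid metabolism (mean -0.00444, median 0.04, test higher) and erythroid genes (-0.08, 0.11, lower) differed in sign between measures and were not called.

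Over the 2849 sex-biased clusters the XY FOXL2+ gonads moved toward the XX level. Of these clusters 1532 (53.8%) changed toward XX, 3 changed away and 1314 did not pass, and 2745 (96.3%) had the direction of XX at any p. With the XY controls split so that the comparisons shared no array, 94.1% to 96.4% of sex-biased clusters had that direction. Of clusters higher in XY 1013 of 1709 (59.3%) changed toward XX, and of clusters higher in XX 519 of 1140 (45.5%). Of the 1532, 421 still differed from XX controls, 1091 did not pass in that comparison, among them Stra8 and Cyp17a1, and 20 lay past the XX level. The 3 that moved away, named after their values were seen, were Vcam1 (1.52, adjusted p = 0.0158), Dcn (0.58, 0.0404) and Abhd3 (-0.44, 0.0457). Vcam1 and Dcn are lower in XX, by -1.29 and -1.43, and encode a cell adhesion molecule and the matrix proteoglycan decorin. The number moving away was 0 without XY control replicate 1 or XX control replicate 2, 1 without XY control replicates 3 or 4, XY FOXL2+ replicate 3 or XX control replicate 4, and 8 without XY FOXL2+ replicates 1 or 2. It was 10 with array weights and 0 with only the 2 groups compared.

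The slope of the FOXL2 effect on the sex difference over these clusters was 0.54, against 0.02 in simulated gonads with no FOXL2 effect and 0.50 to 0.55 with the XY controls split. Over all clusters the changes correlated at 0.771 across genes, which are not independent replicates, against 0.50 in the simulation and 0.659 to 0.711 with split controls. Their covariance was 0.123 against 0.0108 in the simulation, a difference of 0.112, and 0.111 to 0.117 with split controls. Called in both comparisons were 1132 clusters higher and 2368 lower, and 12 and 8 went opposite ways. Independent lists would share 116.2 and 314.1, and 165.5 and 220.5 in opposite ways, but the comparisons share the XY controls, so these are not the values for no FOXL2 effect. In 20 simulated data sets with no FOXL2 effect 0 sex-biased clusters changed toward XX. With split controls 771 to 887 clusters changed toward XX.

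Single XY FOXL2+ gonads differed in how far they had moved. Their positions over all sex-biased clusters were 0.626, 0.815, 0.369 and 0.359 (0.542 ± 0.22, SD, n = 4), whereas the XY controls spanned 0.0787. Cholesterol synthesis genes stood at 1.03 ± 0.0937, Leydig cell genes at 0.785 ± 0.194, meiotic genes at 0.748 ± 0.245, Sertoli genes at 0.566 ± 0.223, postnatal granulosa genes at 0.506 ± 0.434 and fetal granulosa genes at 0.380 ± 0.295. The erythroid score, a measure of blood in the sample, was 10.2, 10.76, 9.03 and 8.64 on the same arrays, with an SD of 0.99 against 0.241 in XY controls.

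**Figure D3:**
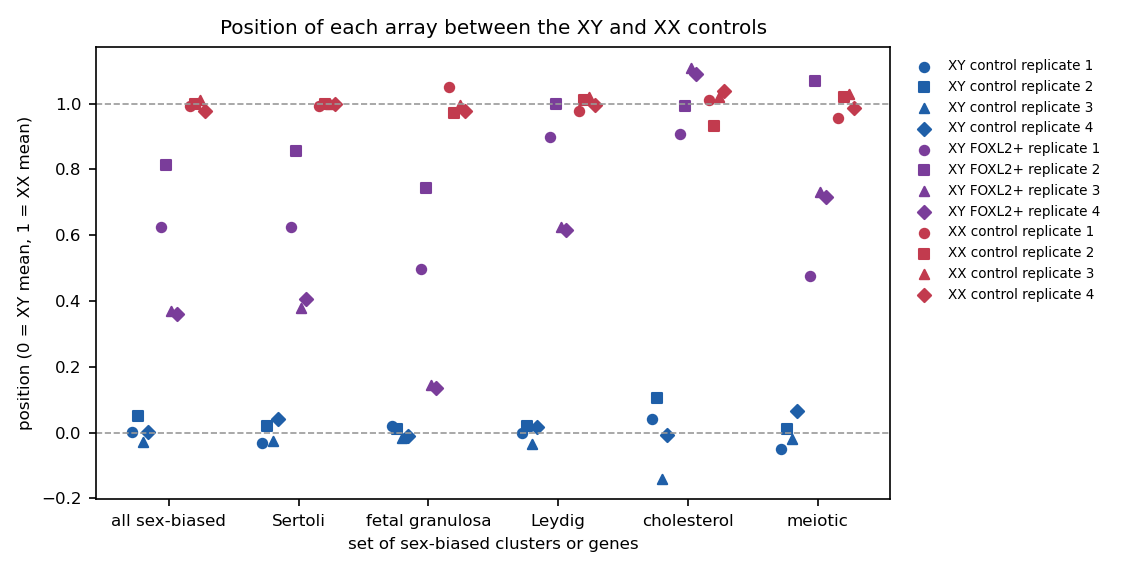
Position of each of the 12 arrays between the XY mean (0) and the XX mean (1) over all sex-biased clusters and over the sex-biased members of 5 lists. Each point is 1 array, and the XY FOXL2+ arrays run from 0.359 to 0.815 over all sex-biased clusters and from 0.907 to 1.11 over cholesterol synthesis genes.

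Some genes left the range between the controls. In XY FOXL2+ gonads 253 clusters were higher than both controls and 223 lower than both, 144 and 104 of them named genes. Array weights gave 504 above both, and the fit on only the 2 groups compared 126 above and 90 below. Thbs1, which encodes the matrix protein thrombospondin 1, read 13.56 ± 0.62 in XY FOXL2+ against 10.19 ± 0.36 in XY and 10.69 ± 0.46 in XX controls (n = 4), changes of 3.38 (SE 0.30, adjusted p = 1.74e-05) and 2.87 (0.000227). Kcnt2 (2.31 and 2.32), the matrix proteoglycan gene Lum (2.12 and 2.27) and Slc26a7 (2.08, adjusted p = 0.00425, and 0.00213 against XX) were also above both. Niban1 (-3.45 and -2.57), Nrn1 (-1.93 and -2.02), Bst2 (-1.71 and -2.25) and Gprc5a (-2.54 and -1.21) lay below both, and Nr5a1 was lower than in XY (-1.68) and in XX controls (-0.44, 0.00532). The number above both was 166 without XY control replicate 3, 403 without XY FOXL2+ replicate 2, and 167 and 160 without XX control replicates 2 and 3. The number below both was 123 and 131 without XY control replicates 1 and 4, 137 and 127 without XY FOXL2+ replicates 3 and 4, and 88, 102 and 98 without XX control replicates 2, 3 and 4.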

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

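None of the tests in this part was chosen after the result was seen. The values of 146 genes, the 26 list scores, the positions, the array medians and 4 classes of control probe sets gave 534 groups of 4 arrays, and in 22 of them (4.12%) 1 array lay far from the other 3 by Dixon's gap ratio at the 95% level. Chance gives about 1 in 20 groups, so the number itself is no sign of a pattern. XY FOXL2+ replicate 1 held 5 of the 22, XY FOXL2+ replicate 2, XY control replicate 2 and XX control replicate 3 held 4 each, and XY FOXL2+ replicates 3 and 4 held none.

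In XY FOXL2+ replicate 1 cell cycle genes and the mitotic score stood above the other arrays of the group. Aurka, a mitotic kinase, read 11.87 there against 10.83 to 10.99, Ccna2, which encodes cyclin A2, 13.71 against 13.02 to 13.07, and the mitotic list score 12.45 against 11.94 to 12.01. Cldn5, a tight junction gene of endothelium, read 9.109 against 8.425 to 8.538, and Eif2s3x, which escapes X inactivation, 13.96 against 12.97 to 13.09. XY FOXL2+ replicate 1 was also extreme in measures of the array itself. Its upper quartile of signal was 8.235 against 8.327 to 8.482 on all other arrays. Control probe sets named MG-1-neg read 7.18 against 7.45 to 7.8, and those named MG-1-pos 11.85 against 11.47 to 11.71. Whether array quality caused its deviations was not tested. XY FOXL2+ replicate 2 was lowest in its group for Emcn (11.13 against 11.41 to 11.43), Hsd11b2 (7.715 against 8.526 to 8.632), Id2 (13.93 against 14.16 to 14.19) and Lefty2 (5.129 against 6.217 to 6.353).

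Among XY controls, replicate 2 was low in Dhh (9.608 against 9.989 to 10.05) and high in Erbb3 (8.911 against 8.549 to 8.597), Nr5a2 (7.283 against 7.137 to 7.155) and Pecam1 (9.987 against 9.711 to 9.757). Replicate 1 was high in Esr2 (6.891 against 6.762 to 6.783) and replicate 3 in Msx2 (6.635 against 6.268 to 6.324). Among XX controls, replicate 3 was high in Aurka (10.72 against 10.33 to 10.37) and low in the endothelial genes Cdh5 (12.92 against 13.15 to 13.17) and Kdr (12.04 against 12.35 to 12.38) and in the macrophage gene Mrc1 (8.052 against 8.29 to 8.32). Replicate 2 was high in Hmgcs1 (14.3 against 14.04 to 14.05) and Id1 (11.95 against 11.46 to 11.54), and replicate 1 in Inhbb (9.921 against 9.794 to 9.814). Of 4 classes of control probe sets left out of the comparisons, 0 had all 4 arrays of XY FOXL2+ or of XX controls above all 4 XY controls by their median.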

How the results depend on the processing

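All alternatives here were planned and none was chosen after the result was seen. No called gene or list changed direction, but the balance of higher and lower counts did: the sex difference went from 41.3% higher to 53.2% after quantile normalization and 50.9% centred, and XY FOXL2+ against XX from 52% to 46.8% and 41.5%. Of 398 counts under an alternative 317 stayed within 1.5 times the main count. Of 5786 values of single genes 5398 kept their side of the threshold, 357 lost and 31 gained the call. The 1575 values for lists include counts of lists whose scores did not overlap between groups. Of these values 1475 kept their side of the threshold or stayed within 1.5 times the main count, 71 lost and 27 gained the call, and 2 such counts moved further. The slope toward XX moved by less than 0.22, the SD of the XY FOXL2+ positions, in 30 of 30. That margin is wide and is not a spread of the slope itself. Counts moved by construction where fewer clusters or another fold threshold were used, and elsewhere the cause was not tested. With clusters of 1 symbol only, 1715 were lower in the FOXL2 effect, 3979 lower in XX than XY, 1445 sex-biased, 877 of those toward XX and 565 not passing, and 138 below both controls. Array weights gave 3668 higher and 3084 lower in XY FOXL2+ than XX, 10 away from XX and 504 above both controls. With only the 2 groups compared, the FOXL2 effect gave 809 higher and 1891 lower, XY FOXL2+ against XX 944 and 972, 0 away from XX, and 126 above and 90 below both controls. A 2-fold threshold left 386 and 721 in the FOXL2 effect, 1140 and 1709 in the sex difference, 566 and 410 in XY FOXL2+ against XX, 936 toward XX, 1 away, and 57 above and 11 below both controls. With no fold threshold for sex bias 11459 clusters were sex-biased, 3500 toward, 20 away and 7939 not passing, and at 4-fold 645, 404, 0 and 241. Split controls gave 810, 855, 820, 771, 773 and 887 toward XX. An estimated correlation left 0 lists higher and 3 lower in the FOXL2 effect, 1 and 5 in the sex difference, and 1 and 1 in XY FOXL2+ against XX. After quantile normalization 5 lists had every XY FOXL2+ score above every XY control, against 3. Quantile normalization also ended the list calls of BMP response, general germ cell and neural crest in XY FOXL2+ against XX. The replicate number as a block gave 1438 higher and 2918 lower in the FOXL2 effect, 4421 and 6484 in the sex difference, 1619 and 1588 in XY FOXL2+ against XX, and 1 away. Of the calls named in the results, the block left out basement membrane (0.0854) in the sex difference, neural crest (0.0529), Star (0.0627) and Lyz2 (0.058) in XY FOXL2+ against XX, and Nr2f2 (0.0826), Smad7 (0.0813), Maf (0.0503), Csf1r (0.0627) and Lama1 (0.0807) in the FOXL2 effect, and it added the immediate early and stress list (0.0486) and Dmrt1 (0.0442) in the sex difference. Little sign was seen that the numbers pair the samples: deviations of same-numbered arrays correlated at -0.091 to 0.18, 2 of 12 pairs over 0.1, and 3 of 12 arrays fitted best with their own number. All 3 were between XY FOXL2+ and XX controls (replicates 1, 3 and 4, at 0.18, 0.072 and 0.11), so pairing of these groups is not excluded. Leaving out each array gave 998 to 1938 higher and 2126 to 3670 lower in the FOXL2 effect, 980 to 2967 and 1032 to 3025 in XY FOXL2+ against XX, 160 to 403 above and 88 to 287 below both controls, and 3 to 6 lists with every score higher (6 without XY control replicate 2). The higher count of the FOXL2 effect was lowest without XY control replicates 3 (998) and 4 (1051), and the other arrays that move a count by over 1.5 times are named beside it in the results. Clusters away from XX were 0 to 8: 0 without XY control 1 or XX control 2, 1 without XY control 3 or 4, XY FOXL2+ 3 or XX control 4, and 8 without XY FOXL2+ 1 or 2. Single arrays ended the calls of 16 of 70 named genes in the FOXL2 effect, 9 of 105 in the sex difference and 20 of 65 in XY FOXL2+ against XX. Changes of genes near the level at which silent genes read, which differs by cluster, are compressed.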

Other observations

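Tests chosen only after the result was seen are those of Xist, of the erythroid score, of Foxl2, of the meiotic genes in replicate 1, of the stricter signal filter and of the gene families. Families were formed from the stems of gene symbols, 337 with at least 8 members. With camera 1 was higher and 1 lower in the FOXL2 effect (Xlr and Igsf), 8 and 6 in the sex difference, and 10 and 19 in XY FOXL2+ against XX, and none was called with an estimated correlation. Collagen genes were lower in the fetal ovary: of 43, 22 were lower and 3 higher in XX than in XY (mean -0.41, adjusted p = 1.53e-05, adjusted p = 0.983 with an estimated correlation), and the mean was -0.338 after quantile normalization and -0.354 after centring (family Col). In XY FOXL2+ 6 fell and 3 rose (mean -0.09, 0.603), and 13 were higher and none lower than in XX (mean 0.32, 2.93e-09, adjusted p = 0.599 with an estimated correlation). Fibrillar collagens were among the 13, with Col1a2 1.11 (0.00679) and Col3a1 0.66 (0.0183) above XX. Col12a1 rose by 2.68 (6.78e-06) in XY FOXL2+ and by 2.83 (2.31e-06) in XX.

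X-linked genes of the Xlr family, whose near-identical copies can share probes and are uncertain one by one, were higher in XX than in XY (11 of 16, mean 1.88, 4.46e-06, adjusted p = 0.983 with an estimated correlation; 1.96 after quantile normalization and 1.93 after centring). In XY FOXL2+ 6 of 16 rose (mean 1.05, 0.00286, adjusted p = 0.986 with an estimated correlation), with Xlr4a at 2.76 (0.00118) against XY controls and -1.68 (0.0318) against XX. Of 14 members of the X-linked homeobox family Rhox, 7 were higher and 1 lower in XX (mean 0.62, 0.0219, adjusted p = 0.906 with an estimated correlation), and 6 were lower in XY FOXL2+ than in XX (mean -0.47, 0.000518, adjusted p = 0.599 with an estimated correlation). Rhox8 fell in XY FOXL2+ (-1.34, 0.00696) and did not pass in the sex difference (-0.61, 0.138). All these families and genes were picked after the data were seen.

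The 4 XY FOXL2+ gonads lay at unequal distances from the ovary, at positions of 0.626, 0.815, 0.369 and 0.359. XX tissue or a swapped label is argued against by Xist, whose highest value among them allows at most 0.297% XX RNA. A difference between arrays in the distribution of their values is argued against as well, since after quantile normalization their range was still 5.93 times that of the XY controls. The clusters were still those chosen from the deposited values, whose own normalization is not known. Quantile normalization would not remove other artifacts of a single array. What stays open is the Foxl2 level and the blood content or stage of the embryo. Foxl2 ordered 6 of 6 pairs of arrays as position did, and the erythroid score ordered 6 of 6 pairs too, and 6 in XY and 4 in XX controls. By chance 1 of 24 orders does so, but that share overstates both matches. The positions 0.369 and 0.359 lie closer together than the XY controls spread (0.0787), so their order is not resolved. Foxl2 is also a sex-biased cluster itself (2.13 in the sex difference), and so is among the clusters that set the position. A candidate explanation is that gonads with more Foxl2 moved further, but the signals of Foxl2 and blood rank these arrays alike and cannot be told apart as explanations, and Foxl2 may include the endogenous gene, as in XX gonads.

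XY FOXL2+ replicate 1 had the lowest meiotic score of its group, although its position was the second nearest to XX. Its meiotic score was -1.3 and its general germ cell score -0.855 relative to the mean of the other 3 arrays. The gap between the lists was thus -0.444 relative to the others, within their SD of 0.6. That SD rests on 3 arrays with gaps of 1.2, 0.314 and 0.0539, too wide to decide whether this sample held fewer germ cells. In the sex difference 3 general germ cell genes were higher and 2 lower, so that list is not a plain count of germ cells. Fewer germ cells thus stay open, as does a lower share of germ cells entering meiosis, which was not tested.

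Steroidogenic genes lay nearer to XX than Sertoli genes in each XY FOXL2+ gonad. A signal floor in XX would pull the Leydig list toward XX. The order held in 4 of 4 arrays with members above the median signal only, but this filter kept 9 of 9 Leydig and 11 of 17 Sertoli genes, so it left the Leydig list as it was. With only the 5 Leydig members above the upper quartile of signal in XX (8.39), set against all Sertoli members, this stricter filter left the order in 4 of 4 arrays (0.941, 1.02, 0.564 and 0.567 against 0.624, 0.857, 0.378 and 0.405), but the Y-linked cluster named Sry reads 9.43 in XX controls and only 1 Leydig gene lies above that there, so neither filter excludes the floor. A difference between arrays in the distribution of their values is argued against, since after quantile normalization the order held in 4 of 4 as well. Other artifacts of single arrays were not tested. A signal floor and a fuller response of Leydig genes cannot be told apart, since the level at which each silent gene reads is not known, and no biological explanation was tested.

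Other splits of the samples were counted for each main result. Every other split of 8 arrays mixes both groups, so a real difference adds to the spread and leaves few calls. The counts therefore show only that the real grouping stands out, with 1 of 35 as the smallest possible share. They do not measure how many calls are false. Of the 35 splits of the 8 XY arrays only the real one, 1 of 35, gave 4698 changed clusters, and the highest other gave 3. For the sex difference the real split, 1 of 35, gave 11459 and the highest other 0, and for XY FOXL2+ against XX the real split, again 1 of 35, gave 3635 and the highest other 1. Sex-biased clusters moved toward XX in 1532 cases in the real split, 1 of 35, and in 2 at most in the others. These clusters were themselves chosen with the same XY controls. Of 100 assignments of the 12 arrays to 3 groups, 3 gave at least the real 476 clusters outside the range: the real one and those with 3500 and 1764, in which the tested group was exactly the 4 XY or the 4 XX controls.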
